A study of Homo sapiens with 6 samples.

How the data were processed

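Total RNA from DLD-1 cells transfected with a control siRNA or an siRNA against lncSLCC1 was sequenced, with 3 libraries per group. The authors deposited one table of raw read counts per gene symbol for each library. TopHat2 version 2.0.11 and HTSeq are named in the submitters' processing notes, with human genome builds hg19 and GRCh37. The strand setting, the annotation release, the library selection and the siRNA sequences are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. HTSeq's summary lines were left out of library sizes and tests. Of all counted reads and alignments, 5.42% to 7.58% per library were assigned to no feature, 8.83% to 10.1% were ambiguous and 12.8% to 13.8% did not align uniquely. Reads shared between near-identical copies are therefore incompletely counted, and some may be assigned to the wrong copy. EEF1A1P5, a pseudogene, was listed at a mean of 6830 CPM by library totals, and how many of these reads came from other copies is not known.

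Groups came from the sample labels. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited, with TMM library sizes, the default expression filter and no covariate, for lncSLCC1 siRNA against control siRNA over all 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. CPM values were computed from the counts with TMM library sizes, and standard errors of log2 fold changes were derived from the fold change and its F statistic. Gene reads per library ran from 12572277 to 15568075, and the common dispersion gave a biological coefficient of variation of 10.9%.

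Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Lists, the tests named so far and the rule for named genes were set before the data were examined. Tests chosen later are marked as such below. Named were RP11-400N13.2, HK2 and AHR; the 10 genes with the largest log2 fold change in each direction with an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, passing over pseudogenes, clone-named genes and genes with no symbol; the 5 genes with the smallest adjusted p in each direction; up to 5 members with the smallest p from each list described; and the annotated neighbours of lncSLCC1. PFKL and DICER1, each the last of a small count, were named after their values were seen. Some genes that the rule selects are not reported here.

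Transcript length, GC content, biotypes and 3' UTR and coding sequences were taken from GENCODE release 29 by gene symbol, directly or through RefSeq synonyms. Each gene was given the length and GC content of its longest transcript, with the basic annotation set taken first. Its longest annotated 3' UTR and coding sequence were used, which may differ from those expressed in these cells. A match was found for 63.2% of the symbols, and 89.5% of tested genes had a length and GC content; the others kept no offset. Words of 6 and 7 bases in 3' UTRs were compared between called genes and other tested genes with a Mantel-Haenszel test over strata of 3' UTR length and GC content, for words expected in at least 20 called genes, with Bonferroni thresholds over 4096 and 16384 words and 100 random gene sets of the same size.

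Alternatives were DESeq2 size factors, library totals, other expression filters, the replicate number as a block, DESeq2 1.42.0, limma-voom, robust empirical Bayes, stricter thresholds, GC content and length offsets, and each library left out in turn. No 2 libraries of one group agreed within sampling noise, and the controls were more scattered. The chi-square statistic per gene ran from 1.87 to 2.005 between lncSLCC1 siRNA libraries. It was 17.5 for control replicates 1 and 2, 31.0 for 1 and 3 and 5.96 for 2 and 3. The main test fitted 1 dispersion per gene over both groups. The tests were tested on simulated counts for lncSLCC1 siRNA against control siRNA, with 200 genes changed, and 14854 genes passing the filter. A planted list of 30 genes raised 1.3-fold was called, and 0 of 32 random lists were. Simulated genes were drawn independently of each other, so this does not test lists whose members vary together. In the data the estimated correlation between members reached 0.859 for ribosomal proteins.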

Results

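RNA-seq libraries of DLD-1 cells, an established human colorectal cancer line, were compared after transfection with a control siRNA or with an siRNA against lncSLCC1, a long non-coding RNA listed in the count tables as RP11-400N13.2. Each group held 3 libraries, and the values were raw read counts per gene symbol. Reads assigned to genes numbered 14873343 to 15568075 in the control siRNA libraries and 12572277 to 15262872 in the lncSLCC1 siRNA libraries. Each library had reads on 22663 to 24109 of the 56638 listed symbols, and 15242 genes had enough reads to be tested. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The design asks which transcripts differ when lncSLCC1 is targeted.

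The targeted RNA was lower in every lncSLCC1 siRNA library than in any control library. RP11-400N13.2 stood at 5.197, 9.31 and 9.04 CPM in control replicates 1, 2 and 3 and at 1.66, 2.62 and 2.10 CPM in lncSLCC1 siRNA replicates 1, 2 and 3. The mean fell from 7.85 ± 2.30 CPM (SD, n = 3) to 2.13 ± 0.479 CPM (SD, n = 3), which left 27.1% of the control level. The log2 fold change was -1.88 (SE 0.264, 95% confidence interval -2.47 to -1.29), with an adjusted p of 0.0027 in edgeR's quasi-likelihood test. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. These levels rest on 73 to 143 reads per control library and 25 to 41 reads per lncSLCC1 siRNA library. RefSeq for assembly GRCh38.p14 names the gene with the synonym lncSLCC1 LINC02474, a long non-coding RNA between LINC02257 and LINC01705, neither of which the count tables list under those names. The nearest annotated protein-coding gene before it in the order of the annotation was DUSP10, which encodes a MAP kinase phosphatase, and its difference did not pass the test (log2 fold change 0.15, SE 0.116, adjusted p = 0.394 by edgeR). Because the files rest on another genome build, no coordinates are given.

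HK2 and AHR had been chosen in advance, since work on lncSLCC1 concerns glycolysis. HK2, which encodes the hexokinase that phosphorylates glucose at the entry to glycolysis, fell from 216 ± 9.44 to 168.7 ± 7.93 CPM (SD, n = 3 each), to 78.1% of the control level. Its log2 fold change was -0.36 (SE 0.076, 95% confidence interval -0.53 to -0.19), and the adjusted p was 0.0159 by edgeR. All 3 lncSLCC1 siRNA libraries, at 161 to 177 CPM, lay below all 3 controls, at 208 to 226 CPM. AHR, the ligand-activated transcription factor aryl hydrocarbon receptor, stood at 117 ± 24.1 CPM in controls and 124 ± 3.51 CPM after lncSLCC1 siRNA (SD, n = 3 each). The difference was smaller than the spread between control libraries (log2 fold change 0.09, SE 0.130, 95% confidence interval -0.20 to 0.38, adjusted p = 0.686 by edgeR), and its sign turned to -0.045 without control replicate 1 and to -0.098 with GC content and length offsets. The HK2 call was lost without control replicate 2 (adjusted p = 0.0658) and without lncSLCC1 siRNA replicate 1 (0.0907), 2 (0.0719) or 3 (0.108), at log2 fold changes of -0.37, -0.36, -0.39 and -0.33.

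**Figure D1:**
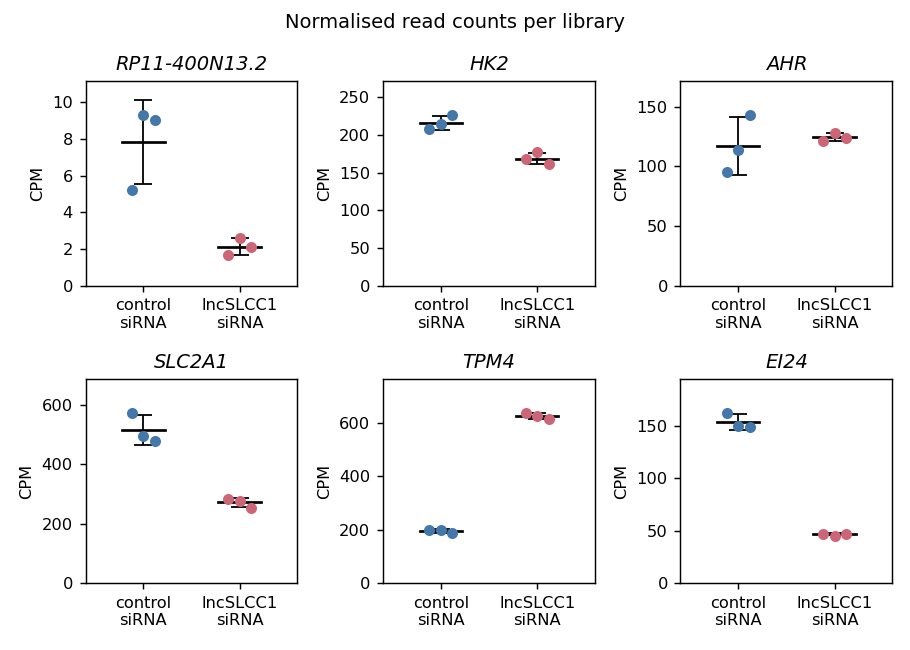
Normalised read counts (CPM, vertical axes starting at 0) of 6 genes in the 3 control siRNA libraries (blue) and the 3 lncSLCC1 siRNA libraries (red); points are libraries, bars are means and whiskers are 1 SD. The groups do not overlap for RP11-400N13.2, HK2, SLC2A1, TPM4 and EI24, whereas AHR in the lncSLCC1 siRNA libraries (121 to 128 CPM) lies inside the control range (95.2 to 143 CPM).

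Across the transcriptome, 984 genes were higher and 1126 were lower after lncSLCC1 siRNA, together 13.8% of the genes tested. Most of the differences were modest, with a median fold of 1.54 among higher genes and 1.40 among lower genes. At least a 2-fold difference was reached by 185 higher and 73 lower genes. Protein-coding genes made up 864 of the higher and 1029 of the lower genes, and 35 long non-coding RNAs were higher and 24 lower among 463 tested.

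The largest rise among genes with at least 5 CPM was that of TPM4, a tropomyosin of actin filaments, from 195.9 ± 5.85 to 626 ± 11.4 CPM (SD, n = 3 each; log2 fold change 1.68, SE 0.071, adjusted p = 7.6e-06 by edgeR). Rises and falls were ranked with pseudogenes, clone-named genes and genes with no symbol passed over. Also among the 10 largest rises were log2 fold changes of 1.39 for AHNAK2, 1.37 for MAP2, which encodes a microtubule-associated protein, 1.31 for EPPK1, which encodes epiplakin, and 1.29 for HSPG2, which encodes the basement membrane proteoglycan perlecan. TP53AIP1, a p53-regulated apoptosis gene, rose by 1.44 and SESN3, a stress-inducible sestrin, by 1.43. The zinc-finger genes ZNF616 and ZNF138 rose by 1.39 and 1.296, and SLC2A10, a glucose transporter gene, rose by 1.27. Standard errors of these 9 values ran from 0.126 to 0.308 and adjusted p-values by edgeR from 0.000297 to 0.024. ZNF138 lost its call by DESeq2 (adjusted p = 0.0508), without control replicate 2 (0.0568) and without lncSLCC1 siRNA replicate 1, 2 or 3 (0.0828, 0.0883 and 0.086). Among genes with the smallest adjusted p, NOLC1, which encodes a nucleolar phosphoprotein, rose by 1.04 (SE 0.069), GANAB, which encodes the catalytic subunit of an endoplasmic reticulum glucosidase, by 1.06 (SE 0.080), BZRAP1 by 1.27 (SE 0.097) and the clone-named GS1-44D20.1 by 1.63 (SE 0.127). The 3' UTRs of TPM4, NOLC1, AHNAK2, ZNF138 and ZNF616 hold the word CGGAGA, which was over-represented among higher genes. SRD5A1 and UBFD1, which are among the 10 largest falls, hold it too. TPM4, SESN3, GANAB and BZRAP1 hold a 7-base site built on CCTTCT, the word over-represented among lower genes.

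The largest fall was that of KRTAP2-3, a keratin-associated protein gene, from 15.2 ± 2.33 to 3.86 ± 0.373 CPM (SD, n = 3 each; log2 fold change -1.97, SE 0.162, adjusted p = 0.000229 by edgeR). Its value is uncertain where reads were shared with near-identical copies of the family. EI24, which encodes an endoplasmic reticulum protein of the autophagy pathway, fell from 153 ± 7.65 to 46.5 ± 0.94 CPM (log2 fold change -1.72, SE 0.081, adjusted p = 1.0e-05 by edgeR). Receptor genes followed, with log2 fold changes of -1.58 (SE 0.083) for TNFRSF21, a death receptor, and -1.55 (SE 0.087) for ADIPOR1, an adiponectin receptor. TXNIP, whose product restrains glucose uptake, fell by 1.42 (SE 0.088) on the log2 scale. ENTPD7, MANEAL, SRD5A1, UBFD1 and MCUR1 completed the 10, at log2 fold changes of -1.47, -1.46, -1.35, -1.34 and -1.31 and adjusted p-values by edgeR of 3.9e-05 to 0.002. Of these 10 genes, 8 have a 3' UTR that holds a 7- or 8-base site built on the word CCTTCT, and MCUR1 holds the word alone, as do SLC2A1 and HK2. Among the falls named below for the 12 lower lists and the AHR targets list, 7- or 8-base sites are in TPI1, PRPS2, SLC7A5, NQO1, KIF2C, MYC, CDK4, CSF1, NFKBIE and CHAC1. CDC45, CCND1 and NOP2 hold the word alone.

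**Figure D2:**
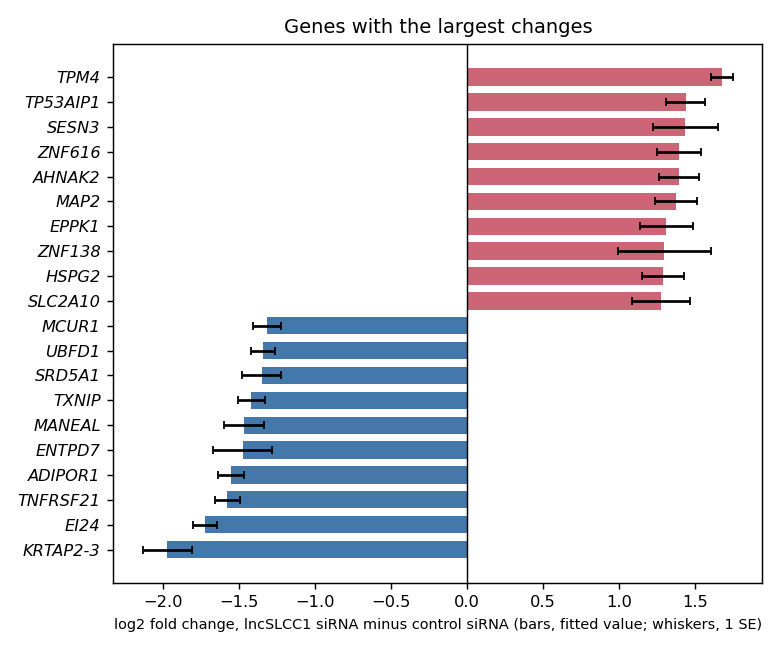
Fitted log2 fold changes (horizontal axis, lncSLCC1 siRNA minus control siRNA) of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) among genes at 5 CPM or more whose groups did not overlap. Pseudogenes, clone-named genes and genes with no symbol were passed over. Whiskers are 1 SE. Values run from 1.27 to 1.68 for rises and from -1.97 to -1.31 for falls.

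The groups did not overlap for 39.0% of tested genes, against 10% by chance, and 4819 genes had an unadjusted p under 0.05. With library totals alone the split moved from 46.6% higher to 63.9% higher (1442 higher, 814 lower), where the median log2 fold change of all genes was 0.0765 in place of 0.0072; with GC content and length offsets it moved to 38.2% (1823 higher, 2948 lower). Each library moved the counts: they were 2112 higher and 2431 lower without control replicate 1, 1614 and 2088 without control replicate 3, 264 and 352 without control replicate 2, and 272 and 318, 222 and 249, and 213 and 244 without lncSLCC1 siRNA replicates 1, 2 and 3.

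Of 33 gene lists fixed in advance, 32 had at least 5 tested members; 12 were lower by camera with a preset correlation of 0.01, and 0 were higher, also at an unadjusted p under 0.05 and by fry. None of the 12 held with an estimated correlation between genes, where adjusted p-values ran from 0.13 to 0.705 and 4 lists had an unadjusted p under 0.05, and 8 of the 12 held by fry. Over the 12 lists, which share some genes, 96 of 363 tested memberships were lower and 5 were higher by edgeR, 114 and 5 by DESeq2, 90 and 5 by limma-voom, and 198 and 8 at an unadjusted p under 0.05. Leaving out control replicate 2 or lncSLCC1 siRNA replicate 1, 2 or 3 ended 31, 34, 40 and 42 calls of named genes, and each of these 4 settings ended those of LDHA, SLC16A3, PFKL, HIST1H1E, RPL32 and RPL35.

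Glycolysis genes were lower as a list (median log2 fold change -0.20, camera adjusted p = 0.00183; adjusted p = 0.705 with an estimated correlation and 0.0766 by fry). In log2 CPM the median was -0.1955, and -0.1261 with library totals. Of 25 tested members, 6 fell and 1 rose, and 18 did not pass the test; adjusted over the list alone, 9 fell and 2 rose. SLC2A1, which encodes the glucose transporter of the plasma membrane, fell from 516 ± 50.5 to 272 ± 15.8 CPM (SD, n = 3 each; log2 fold change -0.92, SE 0.090, adjusted p = 0.00043 by edgeR). TPI1, which encodes triosephosphate isomerase, fell by 0.70 (SE 0.111), LDHA, which encodes a lactate dehydrogenase subunit, by 0.33 (SE 0.074), and SLC16A3, a lactate transporter gene, by 0.42 (SE 0.103), all on the log2 scale. PFKL, a phosphofructokinase gene named because it was the only riser, rose by 0.31 (SE 0.081, adjusted p = 0.0347 by edgeR). In the pentose phosphate pathway 3 of 9 members fell and 0 rose, or 6 and 0 adjusted over the list alone (median -0.24, camera adjusted p = 0.0162; adjusted p = 0.381 with an estimated correlation). The list lost its call without control replicate 1 (adjusted p = 0.0608, median -0.15), control replicate 2 (0.0523, median -0.28) or lncSLCC1 siRNA replicate 3 (0.149, median -0.25). PRPS2, which makes the nucleotide precursor phosphoribosyl pyrophosphate, fell by 1.17 (SE 0.110) on the log2 scale.

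AHR target genes moved both ways and the list did not pass the threshold (camera adjusted p = 0.984; median -0.02, mean 0.06, test direction down). Of 11 tested members, 2 rose and 2 fell, also when adjusted over the list alone. CYP1B1, a cytochrome P450 gene, rose from 17.3 ± 4.25 to 35.2 ± 1.70 CPM (log2 fold change 1.02, SE 0.165), and AHRR, the AHR repressor gene, rose from 15.3 ± 0.994 to 29.01 ± 1.59 CPM (SD, n = 3 each; log2 fold change 0.92, SE 0.106). SLC7A5, an amino acid transporter gene, fell by 0.85 (SE 0.078) and NQO1, a quinone reductase gene, by 0.46 (SE 0.082), with adjusted p-values by edgeR of 0.00032 to 0.00789 over these 4 genes. CYP1A1, at 8.38 ± 1.21 and 6.34 ± 1.02 CPM, did not pass the test (log2 fold change -0.40, SE 0.167, adjusted p = 0.136 by edgeR), but did without control replicate 1 (adjusted p = 0.0466).

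In the S phase list 14 of 34 members fell and 0 rose, or 24 and 0 adjusted over the list alone (median -0.28, camera adjusted p = 4.1e-09; adjusted p = 0.13 with an estimated correlation). CDC45 and CDT1, which act in the firing and licensing of replication origins, fell by 0.62 (SE 0.103) and 0.59 (SE 0.105), and the flap endonuclease gene FEN1 by 0.49 (SE 0.084). In the mitosis list 10 of 34 fell and 0 rose, or 12 and 0 adjusted over the list alone (median -0.17, camera adjusted p = 0.000494; adjusted p = 0.13 with an estimated correlation). In log2 CPM the mitosis median was -0.1642, and -0.0945 with library totals. CDC25B, which encodes a phosphatase that activates the mitotic cyclin-dependent kinase, fell by 1.31 (SE 0.095), KIF2C, a microtubule depolymerase gene, by 1.19 (SE 0.095) and PLK1 by 0.52 (SE 0.084). Of the replication-dependent histone genes 5 of 12 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -0.59, camera adjusted p = 0.000375; adjusted p = 0.364 with an estimated correlation), led by HIST1H4H at -1.08 (SE 0.195) and HIST1H1E at -1.02 (SE 0.235). In log2 CPM the histone median was -0.5575, and -0.3333 over 17 genes with no low-count filter. Histone genes are near-identical copies, so reads shared among them make single values uncertain.

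In the MAPK output list 9 of 22 members fell and 0 rose, or 13 and 0 adjusted over the list alone (median -0.37, camera adjusted p = 4.2e-06; adjusted p = 0.13 with an estimated correlation). The immediate early gene EGR1 fell by 1.28 (SE 0.102), the cyclin gene CCND1 by 0.74 (SE 0.074), MYC by 0.58 (SE 0.084) and the phosphatase gene DUSP6 by 0.47 (SE 0.084). In the MYC targets list 16 of 30 fell and 1 rose, or 20 and 2 adjusted over the list alone (median -0.38, camera adjusted p = 1.5e-06; adjusted p = 0.381 with an estimated correlation). CDK4, a cyclin-dependent kinase gene, fell by 1.09 (SE 0.104) and the ribosome biogenesis genes RRP9 and NOP2 by 0.84 (SE 0.108) and 0.67 (SE 0.092), whereas the riser was NOLC1. In the NF-kB targets list 6 of 17 fell and 0 rose, or 8 and 0 adjusted over the list alone (median -0.13, camera adjusted p = 0.0136; adjusted p = 0.381 with an estimated correlation), led by CSF1, a macrophage growth factor gene, at -1.13 (SE 0.122) and NFKBIE at -0.81 (SE 0.143). In log2 CPM this list's median was -0.1191 over all libraries, -0.2388 and -0.2218 without control replicates 1 and 3, and -0.2151 and -0.1827 without lncSLCC1 siRNA replicates 1 and 3. It was -0.0496 with library totals, -0.2389 with no low-count filter, -0.2058 at a mean CPM of at least 1 and -0.3065 with the GC content and length trend removed.

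In the ATF4 and amino acid response list 12 of 29 members fell and 0 rose, or 16 and 0 adjusted over the list alone (median -0.32, camera adjusted p = 7.5e-06; adjusted p = 0.381 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, fell by 1.148 (SE 0.171), the transcription factor gene ATF3 by 1.08 (SE 0.118), SHMT2, a mitochondrial serine enzyme gene, by 0.78 (SE 0.090) and the asparagine synthetase gene ASNS by 0.52 (SE 0.084). In the NRF2 targets list 5 of 22 fell and 2 rose, or 10 and 2 adjusted over the list alone (median -0.23, camera adjusted p = 0.0265; adjusted p = 0.606 with an estimated correlation and 0.108 by fry). The list lost its call without lncSLCC1 siRNA replicate 2 (adjusted p = 0.0839, median -0.21). The risers were ABCC3, a transporter gene, at 1.06 (SE 0.094) and ME1, the malic enzyme gene, at 0.53 (SE 0.110).

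Ribosomal protein genes were lower as a list by a small amount (median -0.30, camera adjusted p = 2.4e-09; adjusted p = 0.705 with an estimated correlation and 0.2 by fry). Of 75 tested, 5 fell and 0 rose, or 34 and 0 adjusted over the list alone. RPL32, at -0.49 (SE 0.132), and RPL35, at -0.49 (SE 0.130), were among the 5. Oxidative phosphorylation genes were lower likewise (median -0.23, camera adjusted p = 0.000132; adjusted p = 0.705 with an estimated correlation and 0.233 by fry). There 5 of 54 fell and 1 rose, or 4 and 1 adjusted over the list alone, with ATP5B, an ATP synthase subunit gene, at -0.45 (SE 0.094). Ribosomal protein genes took 4.81%, 4.06% and 3.57% of the gene reads of control replicates 1, 2 and 3 and 3.62%, 3.47% and 3.63% of those of lncSLCC1 siRNA replicates 1, 2 and 3, so control replicate 3 lay inside the range of the lncSLCC1 siRNA libraries. Without control replicate 1 the list medians in log2 CPM went from -0.2963 to -0.165 for ribosomal proteins and from -0.2174 to -0.1007 for oxidative phosphorylation, both still past the camera threshold (adjusted p = 3.4e-06 and 0.00847).

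**Figure D3:**
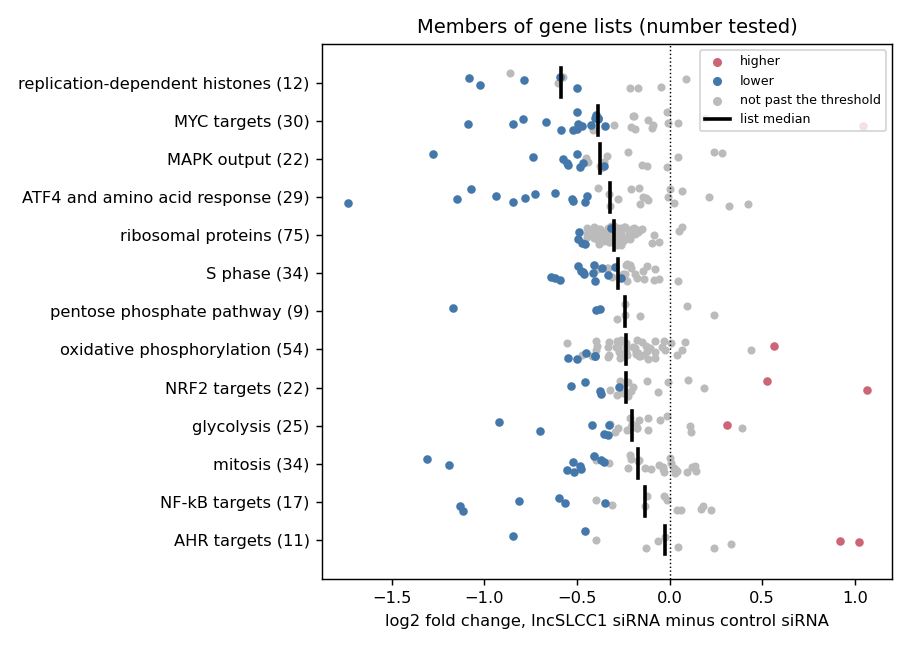
Log2 fold changes (horizontal axis, lncSLCC1 siRNA minus control siRNA) of every tested member of the 12 lists lower by camera and of the AHR targets list, with the number tested in brackets; each point is a gene, red for higher, blue for lower and grey for not past the threshold, and vertical bars are list medians. Medians of the 12 lists run from -0.59 for replication-dependent histones to -0.13 for NF-kB targets, and the AHR targets have 2 genes on each side.

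The other 19 tested lists did not pass the camera threshold, and with AHR targets their adjusted p-values ran from 0.122 to 0.993. By fry, TGF-beta targets and YAP targets were lower (adjusted p = 0.0391 each). By camera, TGF-beta targets were lower with no low-count filter (0.0497) and YAP targets without control replicate 1 (0.0397) and with the GC content and length trend removed (0.0463). The interferon response list, which responds to double-stranded RNA, had 0 higher and 0 lower genes among 30 tested, also when adjusted over the list alone and by DESeq2 and limma-voom, and 5 genes at an unadjusted p under 0.05 (median -0.0016, mean 0.03, camera adjusted p = 0.86). Hypoxia response genes had 1 higher and 1 lower of 20 (camera adjusted p = 0.977), and p53 targets had 1 higher and 6 lower of 23 (camera adjusted p = 0.417). Of leukocyte markers 3 of 20 had enough reads to be tested and of fibroblast and endothelial markers 5 of 17. In simulated counts, the test recovered 78% of 100 genes changed 2-fold and 41% of 100 genes changed 1.5-fold. These shares need not hold for the data, where 2110 genes were called and the controls were more scattered than the lncSLCC1 siRNA libraries. They therefore do not show how many changed genes the test missed here.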

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

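Added after the data were seen were the tests on controls 2 and 3 with GC content and length offsets, the lists with that trend removed, and the lists limited to genes whose 3' UTR was searched and lacks the 6-base word. The targeted RNA kept its direction and its call under all 17 alternatives run, with log2 fold changes of -2.10 to -1.73. The counts were 1600 higher and 1672 lower genes with no low-count filter, where 30025 genes were tested. They were 1823 higher and 2948 lower with GC content and length offsets, and 1652 and 2767 with the replicate block and these offsets. With controls 2 and 3 alone and the offsets they were 2162 and 3554. By stricter construction they were 251 and 327 at an adjusted p under 0.01 and 185 and 73 at 2-fold or more. By glmTreat against 1.2-fold, also stricter, they were 252 and 262. Leaving out one library gave 213 to 2112 higher and 244 to 2431 lower genes, the most without control replicate 1. Of the higher and lower calls, 98.8% and 99.4% recurred without control replicate 1 and 91.2% and 97.0% without control replicate 3, but 26.6% and 31.2% without control replicate 2, and 27.4% and 28.1%, 22.5% and 22.1%, and 21.3% and 21.7% without lncSLCC1 siRNA replicates 1, 2 and 3. Same-numbered libraries did not deviate together (correlations across genes of 0.09, 0.00 and -0.02), so the numbers were not taken to pair them; the replicate block gave 993 higher and 1059 lower genes. The number of changed lists fell to 0 with an estimated correlation. The glycolysis list lost its call with an estimated correlation (adjusted p = 0.705) and by fry (0.0766). For AHR targets the direction turned by fry (adjusted p = 0.986) and without control replicates 2 (0.956) and 3 (0.989) and lncSLCC1 siRNA replicate 3 (0.968) but not without control replicate 1 (0.916), and no setting called the list. AHR's log2 fold change turned to -0.045 without control replicate 1 (leave-one-out range -0.045 to 0.25), -0.098 with GC content and length offsets, -0.095 with the block and offsets and -0.049 with controls 2 and 3 and offsets. Over 98 named genes, AHR among them and the targeted RNA not, 1486 of 1666 values kept side and direction, 162 lost the call, most of them without control replicate 2 or a lncSLCC1 siRNA library, 14 gained it and 4, all of AHR, reversed. Causes were not tested except where stated. Depth limits the targeted RNA, read 25 to 143 times per library.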

Other observations

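The tests of seed-type words among higher genes and of the order of site types were chosen after the result was seen, as were the gene families by symbol prefix, the lists without genes holding a word, the lists with a length and GC trend removed and the tests of trend and control replicate 1 on the oxidative phosphorylation list. The bar of 1 SE from 0 for differences of library medians was also set after these values were seen. The 35 families were protein-coding genes sharing a symbol prefix, each with at least 30 tested members. More ZNF zinc-finger genes, mostly transcriptional repressors, rose than among other coding genes, and so did more KIAA genes. KIAA genes share a naming scheme, and their transcript lengths were not compared with those of other genes. Long transcripts rose more often in general (10.9% of the longest 2730 genes against 2.49% of the shortest 2731). Of ZNF genes 58 of 381 rose and 7 fell (median log2 fold change 0.24; Fisher's exact test over 70 tests, adjusted p = 5.3e-07 for rises and 1.8e-06 for the few falls), and of KIAA genes 21 of 72 rose and 4 fell (median 0.24, adjusted p = 5.3e-07 for rises). With GC content and length offsets 90 ZNF genes rose and 28 fell (median 0.15) and 24 KIAA genes rose and 10 fell (median 0.11). With these offsets falls were also more frequent in the RPL (24 of 48), RPS (20 of 41) and UBE (17 of 38) families and fewer among CCDC genes (9 of 103), and rises were fewer among MRPL genes (0 of 46). In the main test falls numbered 3 in RPL, 2 in RPS, 8 in UBE and 3 in CCDC, and rises 0 in MRPL. None of these passed Fisher's exact test there, where UBE had the lowest adjusted p of them, 0.165. The ZNF and KIAA medians stayed above 0 with DESeq2 size factors (0.24 for both) and library totals (0.30 for both), and fell to 0.13 and 0.12 without control replicate 1 and to 0.10 and 0.09 with controls 2 and 3 alone and the offsets. Without control replicate 3 the KIAA median was 0.36. ZNF rises numbered 92 without control replicate 1 and 98 without control replicate 3, but 12 without control replicate 2 and 10, 8 and 5 without lncSLCC1 siRNA replicates 1, 2 and 3; KIAA rises numbered 23 and 29, but 3 and 4, 3 and 4. Genes of one family are not independent.

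RNA interference genes went both ways: of 13 tested, AGO4 rose by 0.77 (SE 0.143) on the log2 scale, TNRC6B by 0.51 (SE 0.113) and DROSHA by 0.35 (SE 0.076), while TNRC6A (-0.42, SE 0.095), XPO5 (-0.30, SE 0.078) and DICER1 (-0.47, SE 0.135) fell, and the list did not pass the threshold (camera adjusted p = 0.977). XPO5 and DICER1 lost their calls with library totals (adjusted p = 0.0539 and 0.104), and the 6 genes each lost theirs when some of control replicates 2 and 3 and the lncSLCC1 siRNA libraries were left out singly. TNRC6A, XPO5 and DICER1 hold a 7-base site built on CCTTCT, but so does TNRC6B, and AGO4 holds the word alone. COL4A1 and COL4A2, collagen genes that share a promoter region, moved apart, at 0.97 (SE 0.177) and -1.29 (SE 0.123), with adjusted p-values by edgeR of 0.00837 and 0.000364, and COL4A2 holds the word alone; the COL4A1 call was lost without lncSLCC1 siRNA replicate 3, and the TGF-beta targets list that holds both did not pass the threshold by camera (adjusted p = 0.13), though it did by fry (0.0391) and by camera with no low-count filter (0.0497).

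The 3' UTR word with the highest z among genes lower after lncSLCC1 siRNA was CCCTTCT. Weaker words without CCTTCT also passed the thresholds, among them TCTAATA (z = 5.5) and the AT-rich TATTTA (z = 5.2). Random gene sets reached 4.89 for words of 6 bases. The cause of these weaker words was not tested. CCCTTCT was held by 361 lower genes against 211 expected (z = 13.1, where 100 random gene sets reached 5.15), as a seed-type effect of the lncSLCC1 siRNA on other transcripts would give; its sequence is not given in the sources used here. Site types built on a word chosen in the same genes would partly restate that choice, so the genes were split at random into equal parts, and the word was chosen in one part and the site types counted in the other. Over 100 such splits, 96 chose CCCTTCT, and in the part not used for choosing the median lower share was 22.17% with the 8-base site (range 10.6% to 27.47%), 13.09% and 9.88% with the 7-base sites to position 8 and with A, 7.894% with the 6-base word and 6.002% with none (range 5.3% to 8.102%). The full order held in 91 of the splits. These shares are not adjusted for 3' UTR length or GC content. Over all genes searched, the median 3' UTR length was 3130 bases with the 8-base site and 755 with none. Sites of 7 or 8 bases were in 431 of 1027 lower genes against 262 expected from 3' UTR length and GC content, an excess of 16.5% of them. The word was chosen in these same genes, so the excess may be too large. A seed-type effect may account for a part of the falls of about that size. The part may be larger among larger falls. Such sites were in 173 of 306 genes (56.5%) that fell at least 1.5-fold and in 33 of 60 (55%) that fell at least 2-fold. Of all tested genes 25.7% held one, and these shares are not adjusted for 3' UTR length and GC content. The interferon list gave no sign that the groups differed in a response to double-stranded RNA (median -0.0016). Both groups received an siRNA, so a response common to both would not show here. Without genes holding the word, 9 of the 12 lower lists stayed past the camera threshold at the preset correlation. This argues against sites in list members as the whole cause of those 9. With no gene left out, none of the 12 held with an estimated correlation, so the argument goes no further than the preset one. Of these, the histone list kept less of its size, with a median in log2 CPM of -0.5575 over 12 genes before and -0.2122 over 7 after (adjusted p = 0.0241), so sites or the genes not searched, which this setting also left out, may account for part of it. The other 3 lists lost their calls: pentose phosphate and NRF2 at medians about as large over fewer genes (-0.2388 over 9 and -0.2575 over 6; -0.229 over 22 and -0.2214 over 13), which supports no effect of sites, and NF-kB at -0.1191 over 17 and -0.0794 over 8. Effects passed on from genes with sites, and an effect of lncSLCC1 itself, stay open and were not tested. In 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 2110 genes and the highest other gave 0 by edgeR (69 to 596 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05.

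The genes higher after lncSLCC1 siRNA had a weaker word, CCGGAGA (z = 5.68 against 4.96 over random sets, and -0.77 among lower genes), built on CGGAGA. Relief from a seed-type effect of the control siRNA is a candidate explanation for a small part of the rises. CGGAGA was held by 156 higher genes against 104 expected, but it was chosen in these same genes, so the excess partly restates that choice. No genes were held out for this word, and the search was not repeated without the ZNF genes. For the ZNF genes, sites in repeated coding sequence were tested too. The partial rank correlation of log2 fold change with the number of CGGAGA, given coding length, was -0.046 (bootstrap SE 0.052) over 381 genes. It lay near the middle of similarly frequent words (51.1% lay below it) and under the 0.212 that marks their top 5%. Only a value at or below their median, -0.053, had been set in advance to count against such sites, and -0.046 just missed it. The word was absent from 231 of these coding sequences, which limits the test. It gave no sign of such sites as the cause but does not decide. Other causes of the ZNF rises were not tested.

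The lower ribosomal protein and oxidative phosphorylation genes are short transcripts, and short transcripts were lower in general (median log2 fold change -0.12 among the shortest 2731 genes and 0.12 among the longest 2730). This trend differed between the controls. The correlation across genes of a library's deviation with log2 length was -0.316, -0.119 and 0.205 in control replicates 1, 2 and 3. It was 0.097, 0.192 and 0.126 in lncSLCC1 siRNA replicates 1, 2 and 3, so control replicate 3 lay beyond all of these. With each library's trend with length and GC content removed, the ribosomal list median was -0.2352, with a difference of library medians of -0.23 (SE 0.083) against -0.29 (SE 0.144) before, and the list stayed past the camera threshold at the preset correlation (adjusted p = 6.1e-07). The oxidative phosphorylation list went from -0.2174 to -0.1821 and stayed past the threshold (adjusted p = 0.00124), with a difference of library medians of -0.17 (SE 0.089) against -0.22 (SE 0.131) before. With an estimated correlation (0.859 for ribosomal proteins and 0.497 for oxidative phosphorylation), neither call held even before the removal (adjusted p = 0.705 for both). Neither held by fry (0.2 and 0.233). The comparison therefore rests on the library medians, which do not count genes as independent. Both differences stayed below 0 by more than their SE after the removal. With 3 libraries per group that bar is weak, so it is not decided whether the trend as fitted took up the whole difference. The fit took each gene's longest transcript, and the longest 3' UTRs annotated for RPL37 and RPS29 had 7242 and 6828 bases. It may therefore miss a trend with the lengths expressed in these cells. A trend of transcript length and GC content cannot be excluded as the whole cause. For oxidative phosphorylation the difference also lay within 2 SE of 0 before and after the removal. Without control replicate 1 the medians were -0.165 for ribosomal proteins and -0.1007 for oxidative phosphorylation, with differences of library medians of -0.16 (SE 0.106) and -0.12 (SE 0.088), between what that library alone and a shared difference would give, and these cannot be told apart with 2 controls left. A biological difference after lncSLCC1 siRNA stays open, untested.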
